A study of Mus musculus with 2 samples.

How the data were processed

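Neural tube tissue from B6NCrl mouse embryos at embryonic day 15.5 was assayed by ChIP-seq with an antibody against H3K27me3, per the labels, in 2 biological replicates that pooled 78 and 62 embryos of both sexes. Each replicate combined 2 technical replicates, and DNA of 300 to 500 bp was selected, per the labels. The 2 pools were the only samples and formed 1 group, so tests over genes measure how genes differ within this tissue and the spread of 2 pools is the only biological error.

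The authors deposited 4 peak lists on the mm10 build. Per the text files deposited with them, 1 list was called on each replicate's filtered alignments with 2 control alignments, a pooled list was called on both replicates together with the same controls, and a replicated list was derived from the pooled list and the 2 replicate lists. For each peak the deposited lists give its position, a ratio of enrichment over control, -log10 of a p-value and -log10 of a q-value, all computed by the authors' peak caller. The aligner, the peak caller, their versions and the threshold are not given in the sources used here; all deposited -log10 p values were at least 2. The lists carry no read counts, so the depth per sample is unknown, no interval that needs it is given, and a longer list may reflect deeper sequencing as well as more enriched sequence. Calling peaks per replicate means that a difference between the 2 lists can be a difference in where the threshold fell. The enrichment of a peak is the authors' value and was used to describe, rank and filter peaks within a list.

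The lists were checked before use. All 35790 replicated peaks were peaks of the pooled list, with the pooled enrichment; 24554 of them (68.6%) were overlapped by a peak in each replicate's own list, 7878 in replicate 1 alone, 2652 in replicate 2 alone and 706 in neither. A peak in the replicated list is therefore not always a peak called in both replicates, and an alternative that kept the 24554 peaks was added after the data had been examined. No peak lay beyond a chromosome end and no peaks overlapped within a list. Peaks were found on chromosomes 1 to 19 and X, so genes of these 20 chromosomes were analysed.

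Gene positions came from the GENCODE M21 annotation of the same build. Of 21755 protein-coding genes, 21728 were used after leaving out 27 that shared a symbol with a longer gene. A gene was called marked when a replicated peak overlapped the 1 kb on either side of the gene's 5 prime end by at least 1 bp. The level at a gene is the percent of the 10 kb around its start (5 kb on each side) covered by peaks, given as the mean and SD of the 2 replicates. A covered base means only that the authors' caller placed a peak there. Promoter CpG content was the observed over expected CpG ratio of the 1000 bp around the start, with 0.6 as the limit for CpG-rich. Features were assigned in the order promoter, exon, intron and intergenic, over sequence without gaps. Peaks within 3 kb were merged into domains.

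The 27 gene lists, the tests and the rule for naming genes were fixed before the data were examined, and all 447 genes written by hand into the lists were found in the annotation. Each list was tested against all other protein-coding genes with a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 27 lists and a threshold of 0.05; 3 pairs of lists were compared with each other in the same way. Genes in a cluster are not independent, so members within 100 kb were also counted as 1 locus. Peak sharing was set against 20 shuffles of peaks within chromosomes, and no p-value was taken over peaks or bases.

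Genes were named by this rule: for each list, the 3 marked members with the greatest coverage, up to 3 members with the lowest coverage where under 50% of the list was marked (ties by name), and every marked member where 5 or fewer were marked; over all genes, the 10 widest domains and the 10 strongest replicated peaks. Other genes named, such as Hoxa13, the marked neural progenitor genes past the first 3 and the unmarked exceptions of a list, were chosen after their values were seen. Coordinates are 1-based on mm10.

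Alternatives were each replicate's list alone, the pooled list, a -log10 q of at least 2, an enrichment of at least 4, peaks of at least 500 bp, promoter windows of 0.5 and 2.5 kb, any annotated transcript start, at least 500 bp of the promoter window, CpG-rich promoters only, 10000 random lists matched on CpG decile, a CpG limit of 0.75, overlap of at least 50% of a peak, equal numbers of peaks, and merging distances of 1 and 10 kb. Lists without chromosome X were added after the data had been examined. Self-tests on simulated data gave coverage equal to that of bedtools at all 21728 gene windows and recovered a set share of 40% of shared peaks. In simulated lists of the same sizes, 3.11% were called at a true odds ratio of 1, 81.9% at 5 and 99.4% at 20. Each list was simulated at only 1 of these ratios, so a rate does not hold for every list size. No ratio below 1 was simulated, so the rates do not cover lists marked less often. The simulation drew each gene independently, so these rates do not cover lists of clustered genes. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and bedtools 2.31.1.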

Results

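H3K27me3, the trimethylation of lysine 27 on histone H3 that Polycomb repressive complex 2 lays down and that marks repressed chromatin, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the neural tube of mouse embryos at embryonic day 15.5. The neural tube is the embryonic structure that gives rise to the brain and spinal cord. The design had 1 group of 2 biological replicates, each a pool of tissue from many B6NCrl embryos of both sexes: 78 embryos in replicate 1 and 62 in replicate 2. With no second tissue, stage or mark, the comparisons were between gene groups, between parts of the genome and between the replicates. Replicate 1 gave 92487 peaks over 37.4 Mb (1.46% of the genome) and replicate 2 gave 51336 peaks over 21.4 Mb (0.836%). A pooled list, called by the authors on both replicates together, held 76003 peaks, and the authors' replicated list, on which the gene counts below rest, held 35790 peaks over 27.9 Mb with a median width of 475 bp. Read depth per sample is unknown, since the peak lists give no read counts.

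The first question was which genes carried the mark at their start. A replicated peak lay within 1 kb of the start of 2979 of 21728 protein-coding genes (13.7%). In the replicates' own lists the share was 17.8% and 13.7%, or 15.8% ± 2.91 (SD, n = 2), and 2671 genes were marked in both. Of 27 gene lists fixed before the data were examined, 17 were marked more often than other genes, 4 less often and 6 did not pass the threshold (two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 27 lists, adjusted p under 0.05). The highest shares were those of the Hox paralogues 10 to 13 and of the Wnt ligands, at 100% each, and of the spinal cord neuron identity factors at 97.1%. The lowest were those of the vomeronasal receptor, cytosolic ribosomal protein and housekeeping genes, at 0%, and of the olfactory receptor genes at 0.353%. The share of all genes depended on peak strength: with peaks of at least 4-fold enrichment it was 4.25%.

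**Figure D1:**
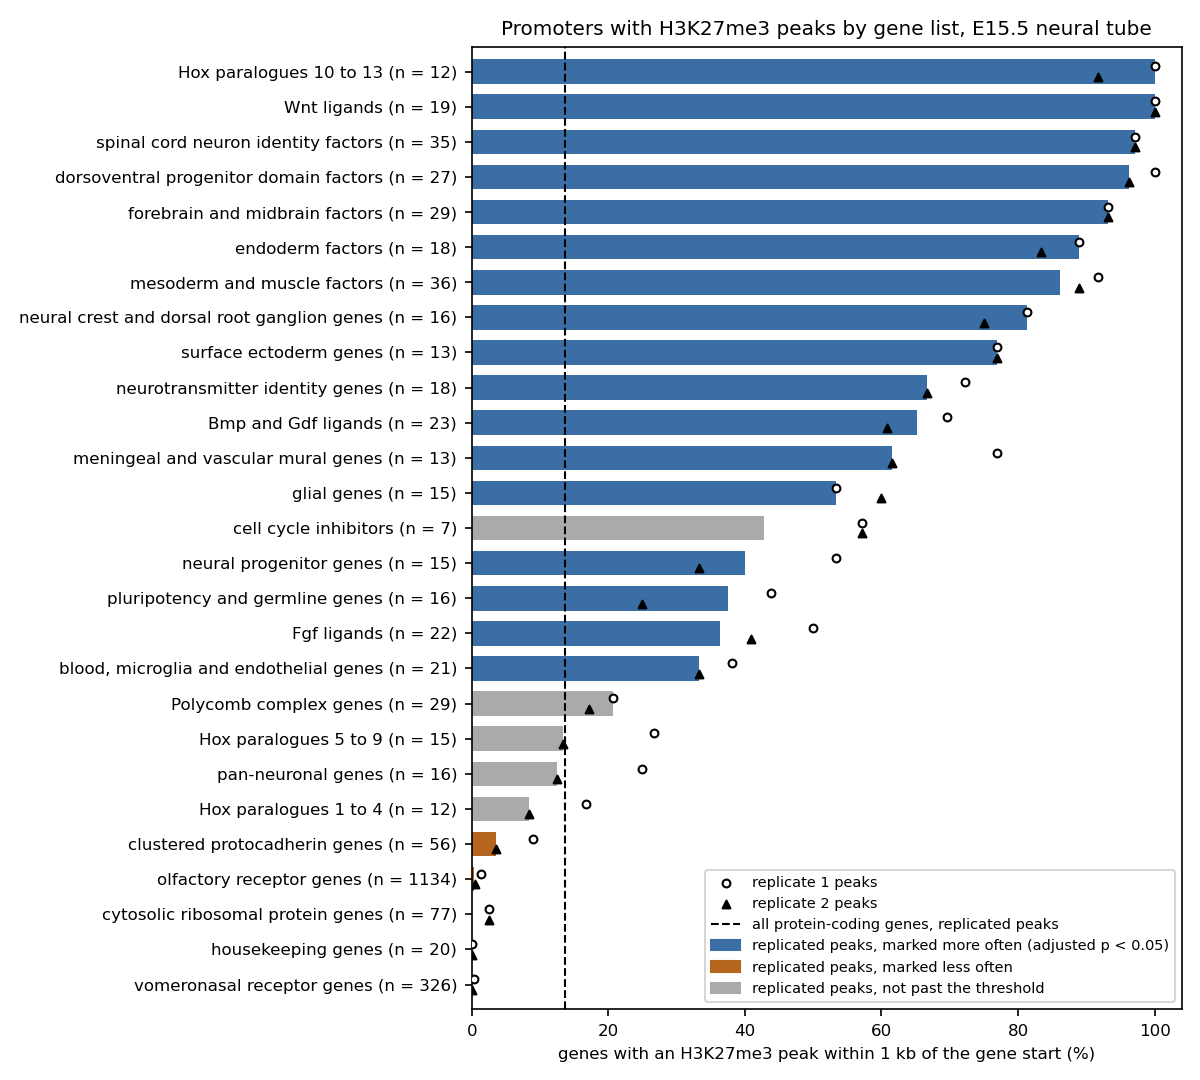
Percent of genes in each of 27 lists with an H3K27me3 peak within 1 kb of the gene start (x axis, %), with the number of genes in each list beside its name. Bars show the replicated peaks, coloured by the outcome of the test; open circles and filled triangles show the peaks of replicates 1 and 2, and the dashed line shows the 13.7% of all protein-coding genes. Hox paralogues 10 to 13 and Wnt ligands lie at 100%, and the receptor, ribosomal and housekeeping lists below 5%.

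The Hox genes, which set position along the head-to-tail axis, were split by paralogue group. Of the 12 genes of paralogue groups 10 to 13, which act in the most posterior segments, 12 were marked (95.8% ± 5.89 over the replicates, n = 2; adjusted exact p = 1.30e-10), against 1 of 12 in groups 1 to 4 (2 of 12 in replicate 1 alone) and 2 of 15 in groups 5 to 9. Coverage by peaks of the 10 kb around the gene start was 89.9% ± 2.64 (SD, n = 2) at Hoxb13 (chromosome 11, 96194316 to 96197447), 84.3% ± 7.83 at Hoxc12 (chromosome 15, 102936757 to 102938609), 83.3% ± 10.3 at Hoxd13 (chromosome 2, 74668310 to 74671599) and 70.8% ± 16.8 at Hoxa13 (chromosome 6, 52257694 to 52260880). Hoxa2 to Hoxa6 and Hoxb2 to Hoxb9 had no peak in that window in either replicate. The single marked gene of groups 1 to 4 was Hoxd1 (28.9% ± 20.0 covered), at the far end of the HoxD cluster. Hoxa1 and Hoxb1 were not marked at the start but held replicated peaks inside the gene. Peaks of replicates 1 and 2 covered 38.9% and 17.5% of the Hoxa1 gene body, and 13.5% and 12.1% of that of Hoxb1. With a promoter window of 2.5 kb, 3 of 12 genes of groups 1 to 4 were marked. In groups 5 to 9 the marked genes were Hoxd9 (26.7% ± 12.9) and Hoxc5 (39.1% ± 20.6), and the annotated start of Hoxc5 (position 102967443) lies beside that of Hoxc10 (102966796), away from the other end of the gene at 103017429.

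The difference between groups 10 to 13 and groups 1 to 4 was 91.7 percentage points (two-sided Fisher's exact test, adjusted p = 2.88e-05 over 3 such comparisons of lists). It ranged from 58.3 to 100 points over the alternative settings. The genes of these groups lie in 4 clusters and are not independent. The p-value here, and that of groups 10 to 13 against other genes, count each gene separately and so overstate the number of independent loci. Groups 1 to 4 and groups 5 to 9 did not differ from other genes (adjusted exact p = 1.0 for both), and their direction relative to other genes turned under 2 and 7 of the 15 alternative settings.

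**Figure D2:**
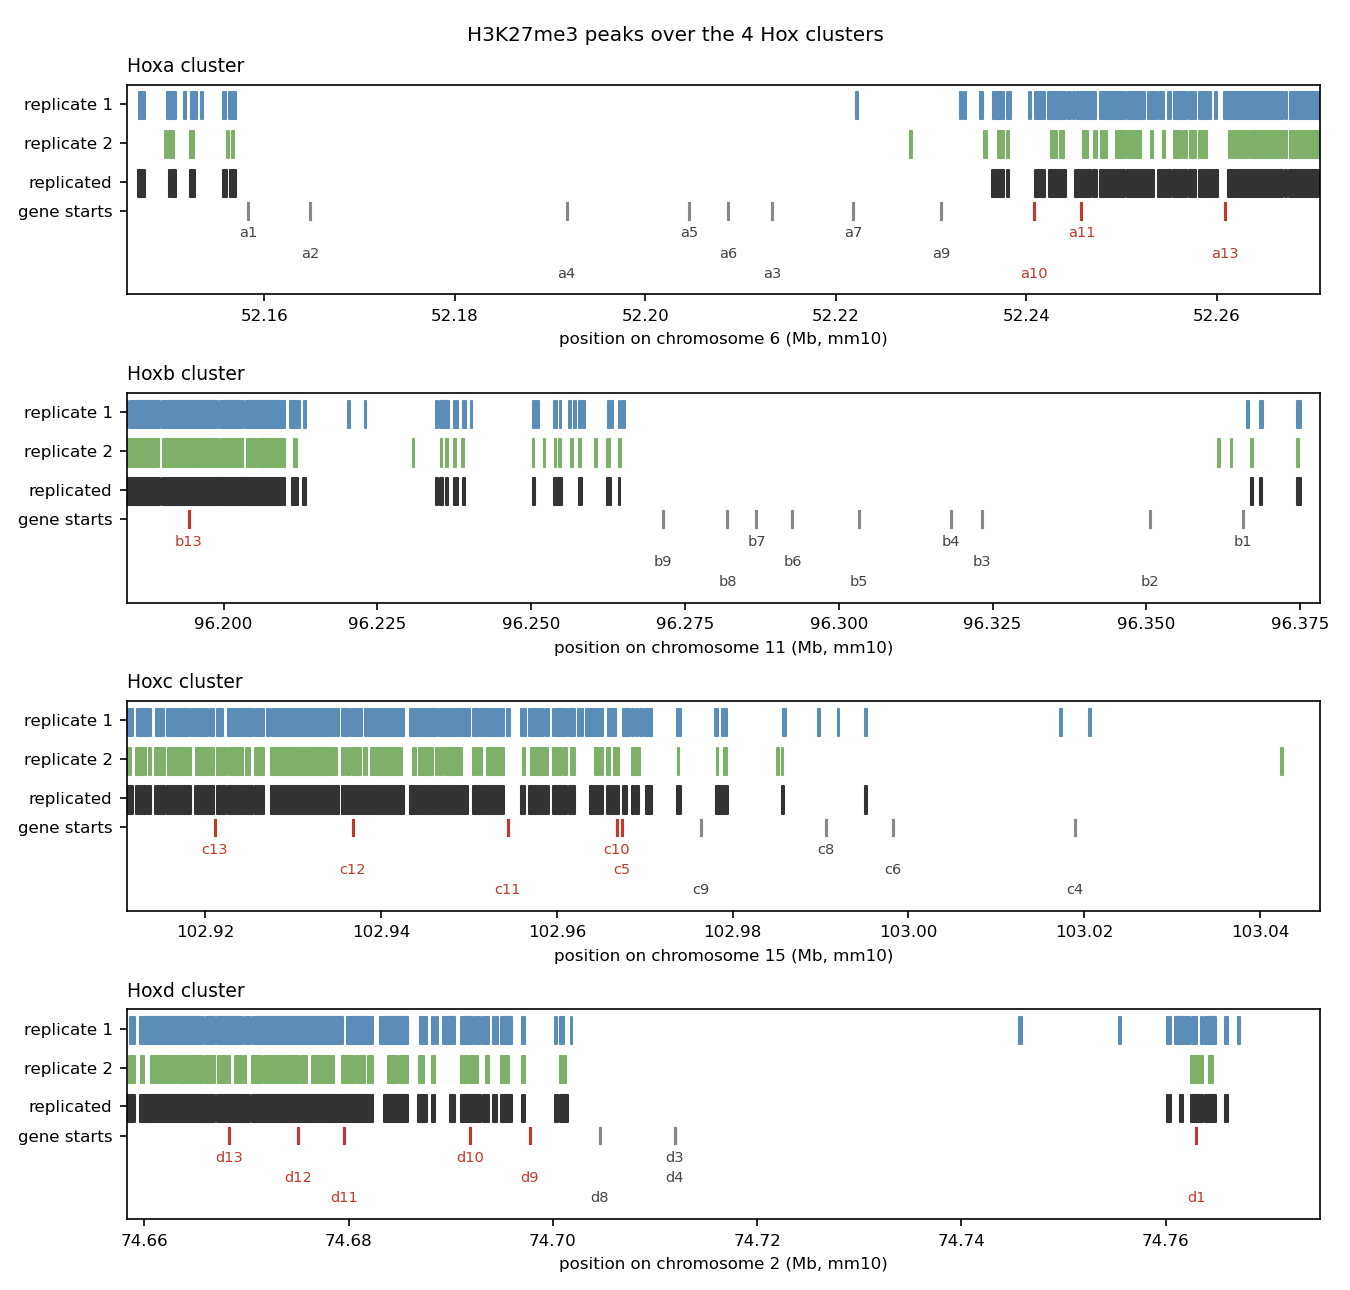
H3K27me3 peaks over the 4 Hox clusters (x axis, position in Mb on the mm10 build), with 1 row each for replicate 1, replicate 2 and the replicated list. Ticks mark annotated gene starts, red where a replicated peak lay within 1 kb; the annotated starts of Hoxa3, Hoxc5, Hoxd3 and Hoxd4 belong to long transcripts and lie beside neighbouring genes. Peaks are densest on the side of groups 10 to 13 in each cluster, with lower coverage at Hoxa10, Hoxc10 and Hoxd10. They leave long gaps from Hoxa2 to Hoxa6 and from Hoxb2 to Hoxb9.

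Genes that pattern the neural tube itself were almost all marked. The tissue was assayed in bulk and expression was not measured. A peak at these genes, or at those of the lists below, therefore does not show which cells carried the mark. Nor does it show that the gene was repressed in the cells that use it. Among the 27 dorsoventral progenitor domain factors, which divide the ventricular zone into bands, 26 were marked (98.2% ± 2.62 over the replicates; odds ratio 165, adjusted exact p = 5.27e-21), with Ascl1 as the exception in the replicated list. Peaks covered 96.6% ± 1.97 of the 10 kb around the start of Neurog1 (chromosome 13, 56250478 to 56252163), a proneural factor of dorsal progenitors, 93.0% ± 9.09 at Olig2 (chromosome 16, 91225457 to 91228677), the motor neuron and oligodendrocyte progenitor factor, and 92.0% ± 1.31 at Gdf7 (chromosome 12, 8297918 to 8301954), a roof plate ligand. Of the 35 spinal cord neuron identity factors, which name the postmitotic classes, 34 were marked (97.1% in each replicate; odds ratio 216, adjusted exact p = 1.59e-27), and Foxp1 was not. The most covered were Gata2, a V2b interneuron factor (95% ± 0.629; chromosome 6, 88193891 to 88207032), Mnx1, a motor neuron factor (92.7% ± 4.65; chromosome 5, 29473034 to 29478470), and Evx1, a V0 interneuron factor (89.0% ± 1.45; chromosome 6, 52313498 to 52318378).

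Factors of the forebrain and midbrain were marked as well, at 27 of 29 (93.1% in each replicate; odds ratio 85.7, adjusted exact p = 6.25e-21), with Hesx1 and Neurod6 unmarked. Whether the dissected tissue held brain as well as spinal cord is not given in the sources used here. Coverage was 98.6% ± 1.95 at Six3 (chromosome 17, 85613608 to 85629302), a factor of the anterior forebrain and eye, 93.8% ± 1.81 at Dlx1 (chromosome 2, 71528113 to 71533981), a factor of ventral forebrain interneurons, and 92.1% ± 3.94 at Vax2 (chromosome 6, 83711264 to 83738313), a factor of the ventral eye. The forebrain and midbrain factors and the spinal factors did not differ in their share of marked genes (difference -4.04 percentage points, two-sided Fisher's exact test, adjusted p = 0.586). With peaks of at least 4-fold enrichment the difference was 10.2 points in the other direction (adjusted exact p = 0.422). The calls of the dorsoventral, spinal and forebrain lists held under the 15 alternative settings.

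Genes of general neural identity were tested against all other genes. Of 15 neural progenitor genes, 6 were marked (43.3% ± 14.1 over the replicates; odds ratio 4.20, adjusted exact p = 0.0164): Pax6 (89.6% ± 12.7 of the window covered), Sox1 (71.8% ± 13.9), Sox2 (37.9% ± 14.6), Hes1, Sox9 and Nes. Fabp7, Msi1 and Notch1 had no peak around the start in either replicate. Of 16 pan-neuronal genes, 2 were marked, Nefl (28.4% ± 9.11), a neurofilament, and Mapt (4.04% ± 0.396), the microtubule protein tau, and Dcx, Elavl4 and Gap43 had no peak there. This list did not differ from other genes (12.5% marked, adjusted exact p = 1.0), and its direction turned under 6 settings. The neural progenitor call was lost under 7 of the 15 settings (adjusted exact or permutation p from 0.0570 to 0.588), among them replicate 2 alone. Progenitor genes were marked less often than mesoderm and muscle factors, by 46.1 percentage points (40% against 86.1%, odds ratio 0.108, two-sided Fisher's exact test, adjusted p = 0.00241), but the difference of 26.1 points with a promoter window of 2.5 kb, or with any annotated transcript start, did not pass (adjusted exact p = 0.0918 each). The progenitor list mixes transcription factors with other genes, such as Nes, Vim and Fabp7, and the mesoderm list holds factors only. Tissue and gene class therefore cannot be told apart in this difference.

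Genes that define transmitter type and glia were also marked more often than other genes. Among 18 neurotransmitter identity genes, 12 were marked (69.4% ± 3.93; odds ratio 12.6, adjusted exact p = 8.07e-07). Coverage was 89.5% ± 4.26 at Fev, a serotonergic factor, 82.3% ± 7.28 at Slc18a3, the vesicular acetylcholine transporter, and 74.7% ± 2.5 at Slc32a1, the vesicular GABA and glycine transporter. Gad1, Slc17a8, Th, Dbh, Tph2 and Ddc were unmarked. Of 15 glial genes, 8 were marked (56.7% ± 4.71; odds ratio 7.21, adjusted exact p = 0.000546), led by Pdgfra (65.1% ± 22.2), the receptor of oligodendrocyte precursors, Gjb6 (48.3% ± 9.12), an astrocyte connexin, and Sox10 (40.7% ± 8.35), the oligodendrocyte and neural crest factor. The glial call was lost with peaks of at least 4-fold enrichment (adjusted exact p = 0.588), where 1 gene remained marked, and among CpG-rich promoters alone (adjusted exact p = 0.453), where the list had 3 genes.

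Factors of mesoderm, endoderm and surface ectoderm were each marked more often than other genes. Of 36 mesoderm and muscle factors, 31 were marked (90.3% ± 1.96; odds ratio 39.4, adjusted exact p = 2.59e-21), with coverage of 93.1% ± 0.445 at Foxf2 (chromosome 13, 31625816 to 31631403), 91.4% ± 4.75 at T (chromosome 17, 8434423 to 8442496), the brachyury factor of early mesoderm and notochord, and 90.7% ± 10.7 at Pitx1 (chromosome 13, 55825051 to 55836192), a hindlimb factor. The muscle regulators Myf5, Myf6 and Myog and the paraxial mesoderm factors Msgn1 and Tbx6 were unmarked in the replicated list. In the replicates' own lists, 33 of the 36 factors were marked in replicate 1 and 32 in replicate 2. Of 18 endoderm factors, 16 were marked (86.1% ± 3.93; odds ratio 50.6, adjusted exact p = 5.91e-12), led by the intestinal factor Cdx2 (95.8% ± 3.35), Neurog3 (92.7% ± 1.52) and the pancreatic factor Pdx1 (85.9% ± 4.24). Of 13 surface ectoderm genes, 10 were marked (76.9% in each replicate; odds ratio 21.1, adjusted exact p = 9.25e-07), led by Ovol1 (88.2% ± 2.17), Tfap2c (83.8% ± 11.1) and Esrp1 (74.3% ± 7.85), and the epidermal genes Trp63, Krt5 and Krt14 were not.

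Genes of tissues that lie next to the neural tube were also marked more often than other genes. The dissected tissue could hold cells of those tissues, but a marked gene does not show whether it did. Of 16 neural crest and dorsal root ganglion genes, 13 were marked (78.1% ± 4.42; odds ratio 27.4, adjusted exact p = 5.95e-09), led by Prdm12 (90% ± 2.17), Tfap2a (84.9% ± 10.5) and Ntrk1 (84.0% ± 5.06), the last being the nerve growth factor receptor of nociceptors. Of 13 meningeal and vascular mural genes, 8 were marked (69.2% ± 10.9; odds ratio 10.1, adjusted exact p = 0.000150), led by Alx4 (85.5% ± 5.75), Tbx2 (77.4% ± 8.22) and Foxd1 (70.8% ± 6.15). Blood, microglia and endothelial genes were marked at 7 of 21 (35.7% ± 3.37; odds ratio 3.15, adjusted exact p = 0.0245); the marked genes included the endothelial factors Fli1 (68.1% ± 4.12) and Sox18 (63.7% ± 4.09) and the adhesion gene Esam (49.9% ± 12.5), whereas Aif1, Csf1r and Cdh5 had no peak at the start in either replicate. That last call was lost under 3 settings (adjusted exact p from 0.0534 to 0.0926): the pooled list, the 2.5 kb window and any annotated transcript start.

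Of the secreted signals, whose families were each tested against other genes and not against each other, every Wnt ligand on the list was marked, 19 of 19 in the replicated list and in each replicate (adjusted exact p = 1.48e-16), led by Wnt10b (91.2% ± 0.622; chromosome 15, 98770712 to 98778150), Wnt1 (82.0% ± 9.07; chromosome 15, 98789857 to 98793837) and Wnt6 (81.3% ± 8.43; chromosome 1, 74771892 to 74785322). Of 23 Bmp and Gdf ligands, 15 were marked (65.2% ± 6.15; odds ratio 11.9, adjusted exact p = 4.45e-08), led by Bmp7 (76.7% ± 8.08), Gdf6 (67.1% ± 10.2) and Inhbb (60.9% ± 9.40). Of 22 Fgf ligands, 8 were marked (45.5% ± 6.43; odds ratio 3.6, adjusted exact p = 0.0105), with coverage of 85.6% ± 6.83 at Fgf8, 65.7% ± 10.9 at Fgf3 and 55.7% ± 8.72 at Fgf17, against none at Fgf10, Fgf12 and Fgf14. The Fgf call was lost against random lists matched on promoter CpG content (adjusted permutation p = 0.0797).

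Among regulators of growth and potency, 6 of 16 pluripotency and germline genes were marked (34.4% ± 13.3; odds ratio 3.78, adjusted exact p = 0.0220). Peaks covered 22.3% ± 1.90 of the window at Pou5f1, 16.3% ± 10.6 at Klf4 and 16.1% ± 1.53 at Esrrb, and the germline genes Dazl and Ddx4 and the pluripotency-associated gene Dppa4 had none. This call was lost under 8 of the 15 settings (adjusted exact or permutation p from 0.116 to 0.588), including replicate 2 alone, where 4 of 16 genes were marked (adjusted exact p = 0.307). Of 7 cell cycle inhibitors, 3 were marked, Cdkn2a (80.3% ± 11.4), Cdkn2b (79.8% ± 5.45) and Cdkn2c (29.3% ± 17.0); the list did not pass (odds ratio 4.72, Fisher's exact test, adjusted p = 0.0721), although it did under 8 settings. Of 29 genes of the Polycomb complexes themselves, 6 were marked (adjusted exact p = 0.311). Cbx8 (70.3% ± 6.90), Pcgf5 (41.7% ± 7.91) and Phf19 (39.6% ± 2.99) were covered, and the core gene Eed and the chromobox genes Cbx6 and Cbx7 had no peak at the start.

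At the other end, large receptor families were nearly free of called peaks. The lists give no signal outside peaks, nor whether reads could be placed at these genes. The mark itself therefore cannot be called absent there. Of 1134 olfactory receptor genes, 4 were marked (0.926% ± 0.686 over the replicates; odds ratio 0.0210, adjusted exact p = 5.06e-66): Olfr63 (6.48% ± 0.113 of the window covered), Olfr12 (4.16% ± 1.05), Olfr750 (3.46% ± 2.41) and Olfr71 (2.24% ± 0.191). None of 326 vomeronasal receptor genes (adjusted exact p = 6.25e-21) and none of 77 cytosolic ribosomal protein genes (adjusted exact p = 3.41e-05) carried a replicated peak. In the replicates' own lists 1 vomeronasal gene was marked in replicate 1, and 2 ribosomal genes in each replicate. The clustered protocadherin genes, which give neurons their surface identity, were marked at 2 of 56, Pcdhgb7 and Pcdhga9 (odds ratio 0.233, adjusted exact p = 0.0378). None of 20 housekeeping genes was marked, which did not pass the threshold (adjusted exact p = 0.116). This is the lowest share possible, so a list of 20 genes could not have passed as marked less often. It did pass under 3 settings (adjusted exact p from 0.0297 to 0.0468): replicate 1 alone, the pooled list and the 2.5 kb window. None of the 20 was marked there either. Only the share of other genes was higher, at 17.86%, 17.32% and 18.85% against 13.72%. The protocadherin call was lost under 5 settings, including replicate 1 alone (5 of 56 marked, adjusted exact p = 0.133) and counting neighbouring genes as 1 locus. The latter left 3 loci, too few for any low share to pass. The ribosomal call was lost with peaks of at least 4-fold enrichment (adjusted exact p = 0.120), where none of 77 genes was marked against 4.27% of other genes. The vomeronasal call was lost only among CpG-rich promoters, which left 1 gene.

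Promoter sequence was compared because H3K27me3 in mammals lies mostly at CpG-rich promoters. Among promoters with an observed over expected CpG ratio of at least 0.6, 1498 of 10059 were marked (14.9%), against 1481 of 11669 others (12.7%). The odds ratio was 1.20 (95% interval 1.11 to 1.30; two-sided Fisher's exact test, p = 2.74e-06). The direction of this small difference was not stable: the odds ratio was 0.949 (exact p = 0.145) with the peaks of replicate 1 alone and 0.770 (exact p = 9.97e-09) when CpG-rich meant a ratio of at least 0.75, and 1.67 with peaks of at least 4-fold enrichment.

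Across the genome, the mark was concentrated at gene starts. Promoters, the 2 kb around gene starts, make up 1.60% of the genome and held 11.5% of the bases in replicated peaks, a 7.18-fold enrichment (6.26 ± 1.10 over the replicates, n = 2). Exons were 2.29-fold enriched (2.14 ± 0.236), introns were near their genomic share at 0.960-fold (0.962 ± 0.0104), and intergenic sequence was depleted at 0.729-fold (0.769 ± 0.0460), although it still held 37.9% of the covered bases. No p-value was taken over bases.

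A small share of marked loci were wide. Merging replicated peaks within 3 kb gave 12792 domains with a median width of 0.902 kb. The 927 domains of at least 10 kb were 7.25% of all domains and made up 46.5% of the merged length. Of these, 503 (54.3%) held the start of a protein-coding gene. The widest, at 154 kb (chromosome 7, 49613033 to 49767440), held the starts of Dbx1, a V0 progenitor factor, and Htatip2, and was covered to 72.6% ± 5.23 by peaks of each replicate. Others held Olig2 (127 kb; chromosome 16, 91121112 to 91248346), its neighbour Olig1 (102 kb; chromosome 16, 91255800 to 91358134), Nkx2-1 (117 kb; chromosome 12, 56430779 to 56547812), Dmbx1 with 6430628N08Rik (103 kb; chromosome 4, 115888914 to 115991616), Nkx1-1 (96.1 kb; chromosome 5, 33424150 to 33520201) and Iqsec2 (118 kb; chromosome X, 152112370 to 152230592; 48.9% ± 4.63 covered). The number of domains of at least 10 kb rested on the list and the merging distance: it was 1683 with replicate 1 alone, 919 with replicate 2 alone, 1696 with the pooled list, 221 with peaks of at least 4-fold enrichment, and 498 and 1708 with merging distances of 1 kb and 10 kb.

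Of the 10 widest domains, 3 held no protein-coding gene start. The first, of 143 kb, lay inside Rnf220 (chromosome 4, 117299653 to 117442810; 66.5% ± 9.39 covered). The second, of 102 kb, overlapped Fto (chromosome 8, 91604883 to 91706825; 38.0% ± 11.6), where the nearest gene start to the middle of the domain was that of Irx3, 146213 bp away. The last, of 93.8 kb, was intergenic with respect to protein-coding genes (chromosome 5, 101486417 to 101580218; 55.3% ± 9.95), with Nkx6-1 nearest at 131678 bp.

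The 10 replicated peaks of the highest enrichment were set against the nearest gene start. Enrichment over control is the value the authors deposited for each peak. The strongest replicated peak spanned the promoter of Helt, a factor of midbrain GABAergic neurons (chromosome 8, 46290066 to 46297302; 9.47-fold, -log10 p of 64.4). The next lay in an intron of Prdm12 (chromosome 2, 31645821 to 31653487; 8.45-fold), in intergenic sequence 151842 bp from Six3 (chromosome 17, 85460557 to 85469916; 8.39-fold) and in an exon of Plekhh3, 4068 bp from the start of Cntnap1 (chromosome 11, 101161600 to 101169509; 8.23-fold). The remaining 6 of the 10 strongest had Ptf1a (8.09-fold), Nkx2-1 (8.02-fold), Otx1 (7.95-fold), Pax1 (7.80-fold), Irx4 (7.74-fold) and Osr1 (7.73-fold) as the nearest gene start, at distances from 1588 bp for Irx4 to 10499 bp for Nkx2-1.

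Chromosomes differed in coverage by more than 3-fold in the replicated list, from 0.528% of chromosome 3 to 1.99% of chromosome 19 (1.99% ± 0.695 over the replicates). Chromosome X, inactivated on 1 copy in female cells, was covered at 1.35% against 1.07% of the autosomes, a ratio of 1.25; the ratio was 1.08 in replicate 1 and 1.38 in replicate 2, or 1.23 ± 0.210. The share of female embryos in each pool is not given in the sources used here, so the ratios cannot be set against it. Few X peaks were strong: 0.566% of them reached 4-fold enrichment, against 9.68% of autosomal peaks. The medians were close (2.71-fold and 2.75-fold). The ratio fell to 0.0847 with peaks of at least 4-fold enrichment and to 0.875 with peaks of at least 500 bp, so the higher coverage of X rested on peaks below these limits. Promoters on X were marked at 12.2% against 13.8% on the autosomes in the replicated list and 17.6% against 17.9% in replicate 1. The direction was the other way at 14.5% against 13.7% in replicate 2 and 17.8% against 17.3% in the pooled list. With the 51336 strongest peaks of each replicate the ratio was 1.01 in replicate 1 and 1.38 in replicate 2, so the excess on X was not seen in replicate 1 at an equal number of peaks.

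**Figure D3:**
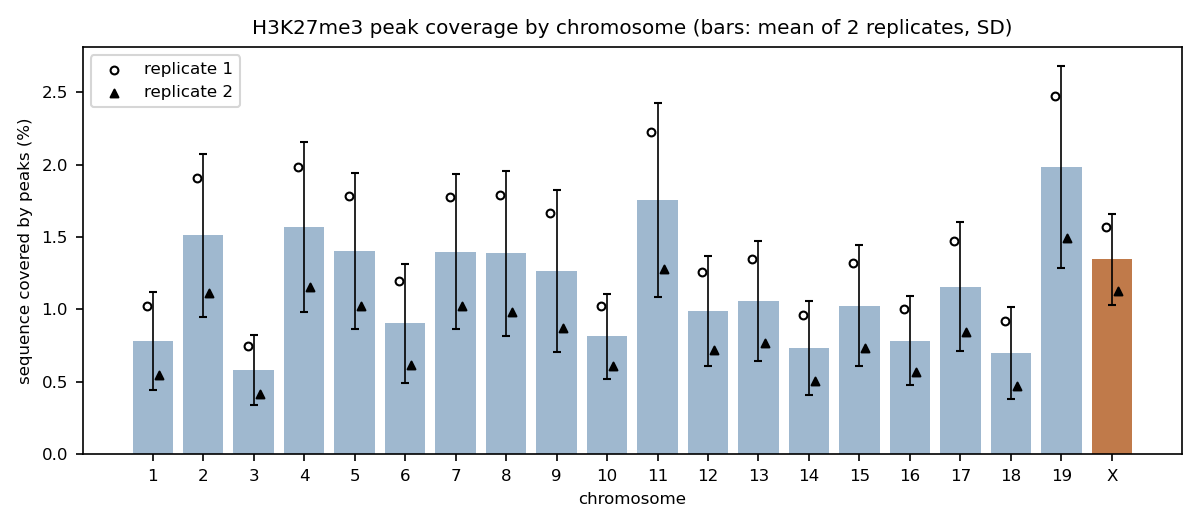
Percent of the sequence of each chromosome covered by H3K27me3 peaks (y axis), as the mean of 2 replicates (bars) with the SD (error bars); open circles show replicate 1 and filled triangles replicate 2. Chromosome 19 has the highest mean, at 1.99%, and chromosome 3 the lowest, at 0.581%; replicate 1 lies above replicate 2 on each chromosome.

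The replicates were compared last, to set how far single peaks can be trusted. Of the peaks of replicate 2, 63.7% overlapped a peak of replicate 1 by at least 1 bp (95% Wilson interval 63.3 to 64.1%), against 3.09% ± 0.0800 after shuffling peaks within chromosomes (20 shuffles). Of the longer list of replicate 1, 31.3% overlapped a peak of replicate 2 (31.0 to 31.6%), against 1.72% ± 0.0452 after shuffling. The intervals treat peaks as independent and cover counting error only. Of peaks of at least 5-fold enrichment, 100% in either replicate were found in the other, against 20.8% of the replicate 1 peaks and 51.9% of the replicate 2 peaks between 2-fold and 3-fold. Below 2-fold the shares were 15% and 60.5%, so overlap in replicate 2 did not rise over the whole range. When both lists were restricted to at least 4-fold enrichment, the share of replicate 1 peaks found was 52.1%. Across 32716 overlapping peaks, which are not independent replicates, log2 enrichment correlated with Spearman's rho of 0.444 and Pearson's r of 0.511. Of genes, 89.6% of those marked in replicate 2 were marked in replicate 1, and 68.9% of those marked in replicate 1 were marked in replicate 2.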

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

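The settings that keep peaks overlapped in both replicates' own lists or leave out chromosome X were chosen after the data had been examined; the others were planned. Of 404 alternative values for the 27 gene lists, 349 kept direction and call, 28 kept direction and lost the call, 11 gained it and 16 turned direction, none of the last for a list that had passed; 13 of the 21 lists that passed did so under each setting run. Without 1 replicate, the share of marked promoters ranged from 13.7 to 17.8%, the CpG odds ratio from 0.949 to 1.11, promoter enrichment from 5.49 to 7.04-fold and wide domains from 919 to 1683; Hox groups 5 to 9 ranged from 13.3 to 26.7% and pan-neuronal genes from 12.5 to 25%, above other genes in replicate 1 alone, Hox groups 1 to 4 from 8.33 to 16.7% and clustered protocadherin genes from 3.57 to 8.93%. With the pooled list, 17.3% of promoters were marked, with 20.0% of Hox groups 5 to 9 and 25% of pan-neuronal genes, a CpG odds ratio of 1.04, promoters 5.90-fold enriched and 1696 wide domains.

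An enrichment of at least 4 gave 4.25% of promoters, 2 lists marked less often in place of 4, 10.2 points between forebrain and spinal factors, 52.1% and 75.5% of replicate 1 and 2 peaks shared, a rho of 0.360, promoters 9.90-fold enriched, an X ratio of 0.0847 and 221 wide domains. With both replicate lists cut to a -log10 q of at least 2, 25.4% and 78.8% of replicate 1 and 2 peaks were shared. Set against the whole list of the other replicate, 43.9% and 85.5% of the peaks at that limit were shared. The same limit put Hox groups 5 to 9 at 13.3%. Peaks of at least 500 bp gave promoters 8.29-fold enriched, an X ratio of 0.875, 588 wide domains and pan-neuronal genes at 12.5%, and the added list of peaks overlapped in both replicates put Hox groups 5 to 9 at 13.3% and pan-neuronal genes at 12.5%. Overlap of at least 50% of the peak gave 22.3% and 54.1% shared and a rho of 0.466, and equal numbers of peaks gave 44.1% and 52.9%. Promoter windows of 0.5 and 2.5 kb marked 10.8% and 18.8% of promoters. The first put the CpG odds ratio at 1.08 and Hox groups 5 to 9 at 13.3%; the second put Hox groups 1 to 4 at 25% and 5 to 9 at 20.0%, and progenitor against mesoderm genes at -26.1 points, as did any transcript start, with Hox groups 1 to 4 at 16.7% and pan-neuronal genes at 18.8%. Requiring 500 bp of the window marked 9.89% of promoters and 6.90% of Polycomb genes. CpG-rich promoters alone left 1 list marked less often and pan-neuronal genes at 20.0%, 1 locus per cluster put Hox groups 5 to 9 at 25%, and a CpG limit of 0.75 turned the odds ratio to 0.770. Merging distances of 1 and 10 kb gave 498 and 1708 wide domains. Fewer or shorter peaks lower such counts by construction; for the other changes the cause was not tested. No paired analysis was possible because there was 1 group. Depth is unknown, so an unmarked gene is a gene with no called peak.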

Other observations

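The gene families of the first paragraph below, the coverage of single gene bodies on chromosome X and the test of an even spread along X were chosen only after the results had been seen; the bounds of the other tests were written before their values were known. A further test written beforehand, of whether the longer list of replicate 1 accounted for its lower X ratio, was run and then left out of the weighed patterns after its value was seen, to keep to 3; at equal numbers of peaks the ratios were 1.01 and 1.38, which met the bound set against that explanation. Outside the 27 lists, genes were grouped by the stem of their symbol, and 259 families of at least 10 genes were tested (two-sided Fisher's exact tests, Benjamini-Hochberg adjusted); 16 were marked more often and 5 less often. Collagen genes (Col) were marked at 23 of 43 (57% ± 1.64 over the replicates, adjusted exact p = 1.01e-07), among them Col13a1, Col4a1, Col4a2 and the cartilage collagen gene Col2a1. Genes of two-pore potassium channels (Kcnk) were marked at 9 of 14 (71.4% ± 10.1, adjusted exact p = 0.00152), integrin alpha chains (Itga) at 8 of 12 (70.8% ± 5.89, adjusted exact p = 0.00237), voltage-gated calcium channel subunits (Cacna) at 8 of 14 (53.6% ± 25.3, with 71.4% in replicate 1 and 35.7% in replicate 2, adjusted exact p = 0.00888) and serotonin receptors (Htr) at 7 of 14, including Htr6, Htr1a and Htr5b (60.7% ± 15.2, adjusted exact p = 0.0277). Zinc finger genes with the stem Zfp were marked at 14 of 393 (4.58% ± 1.80, adjusted exact p = 3.32e-09), histone genes (Hist) at 1 of 67, Hist1h1b (adjusted exact p = 0.0273), and mitochondrial ribosomal proteins of the large subunit (Mrpl) at 0 of 49 (4.08% in each replicate, adjusted exact p = 0.0277). Symbol stems mix unrelated genes in some families, and members of a genomic cluster are not independent.

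Some long non-coding RNA genes carried the mark too, in a count that was not among the planned tests. A replicated peak lay within 1 kb of the start of 886 of 9603 (9.23%), and of 448 of the 7306 whose start lay over 5 kb from any protein-coding gene start (6.13%). Both shares were below the 13.7% of protein-coding genes. No share of random windows was computed, so the shares cannot be set against background. In the replicates' own lists the shares were 12.1% ± 3.67 and 9.32% ± 3.89, the latter from 12.1% in replicate 1 and 6.57% in replicate 2. In the latter group the most covered 10 kb windows were those of Gm16224 (94.8% ± 4.70; chromosome 4, 135143421 to 135144285), Gm27197 (94.4% ± 4.41; chromosome 2, 38347357 to 38348316) and Tlx1os (93.1% ± 7.36; chromosome 19, 45154057 to 45159304), with 1700021F13Rik (92.9% ± 0.665), Tbx3os2 (91.5% ± 4.65) and Sfta3-ps (90.8% ± 2.78) also above 90%; Sfta3-ps lies in the domain that holds Nkx2-1.

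Peaks covered a larger share of X than of the autosomes. Repeated or amplified loci stay open: 28.7% of the 1 Mb bins of X lay above the median autosomal bin, between the bounds of 25% and 75% set for them, and the median X bin had no peak. Called peaks were not spread evenly along X: 27.5% and 29.3% of its bins lay above the autosomal median in replicates 1 and 2. The excess lay in the upper bins (90th percentile 4.94% against 3.29%). These shares met the bound set against an even spread, but a mark too weak to be called would leave bins without peaks. The bins therefore cannot decide whether the mark itself was spread evenly. The excess of peaks lay away from gene starts, with an X to autosome ratio of 1.84 over 5 kb from gene starts against 0.575 within 5 kb. The ratio away from gene starts exceeded the near ratio in replicate 1 (1.39 against 0.575) and replicate 2 (2.01 against 0.627), so that prediction, written beforehand, was met. What accounts for this excess stays open. An inactive X in the female embryos was tested on 6 genes transcribed from the inactive X, with 50 kb on each side, and the prediction failed: they lay at the 96.5th percentile of random sets of X genes (12.7% against 4.72% covered), where a low rank had been predicted and the bound against it was 50. Gene bodies, examined only after that value was seen, held no pooled peak in 5 of the 6 genes, as in 64.8% of 250 other CpG-rich X genes, and their mean coverage of 0.861% against 5.29% ran in the direction of the explanation, untested; the high mean of the windows came mostly from the flanks of Eif2s3x and Kdm5c, the latter 2427 bp from the Iqsec2 domain, so tissue separated by sex would be a more direct test.

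Promoters of low CpG content carried replicated peaks almost as often as CpG-rich ones. Chromosome X alone does not account for it, since the odds ratio was 1.18 without X, under the bound of 1.5. Weak peaks may contribute, but the test could not tell. With peaks of at least 4-fold enrichment the odds ratio was 1.67, between the bounds of 1.5 and 2 set for that explanation. CpG-rich promoters made up 43.4% of those whose strongest peak was 2-fold to 3-fold enriched and 58.4% of those of at least 4-fold. Among promoters without a replicated peak the share was 45.7%. Gene starts annotated away from the CpG island gave 1.51 when any transcript start could count, which lies between the bounds, and genes with more annotated starts have more chances at both a CpG-rich start and a peak. No biological explanation was tested.

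Replicate 1 gave more peaks than replicate 2. Greater sequencing depth of replicate 1 would let weaker enrichment reach a given p-value, and the median enrichment of its peaks with a -log10 p from 2 to 3 was 2.03-fold against 2.20-fold in replicate 2, with replicate 1 lower in each of the 8 ranges of -log10 p examined. This is consistent with depth, but the enrichments are the caller's values from separate lists, and the read numbers that would settle it were not used here. A difference between the 2 pools of embryos stays open and was not tested.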
